A study of Mus musculus with 5 samples.

How the data were processed

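RNA of visceral adipose tissue from male C57BL/6 mice was measured in 5 libraries: 1 control, 2 obesity and 2 obesity with resveratrol. Per the labels' protocols, RNA was extracted with a lipid tissue kit, stranded poly-A libraries were made and paired-end reads of 150 bases were sequenced. Per the labels, the authors made the deposited counts with featureCounts on genome build GRCm39, after quality control with FastQC. The aligner, the annotation release, the strand setting of the counting and the versions of these tools are not given in the sources used here. The deposited table holds raw whole-number counts for 78334 Ensembl mouse gene identifiers in 5 columns, with no normalisation, and 65.7% of the identifiers were given a symbol. Genes are given by name and identifier alone, since the reference at hand was on another genome build.

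Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr by group with a minimum count of 10 and a minimum total of 15, which left 24779 genes, and TMM factors scaled the libraries. A robust quasi-likelihood fit of all 5 libraries gave each comparison an F test, adjusted with Benjamini-Hochberg at 0.05. The lone control library was assumed to vary like the other groups. The SE of a log2 difference was its absolute value divided by the square root of F. A gene at a count of 0 in a group was given a floor of 3 counts per library, from 0.105 to 0.157 CPM, and folds against it are lower bounds. Total counts ranged from 19540961 to 27026597, and 17929 to 22955 genes had 10 or more counts in a library. The biological coefficient of variation was 62.2% over all 5 libraries, 31.9% within the obesity pair and 78.6% within the resveratrol pair.

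Before the data were examined, 48 gene lists, the rule for genes to be named, the tests and the alternatives were fixed. Lists with at least 5 tested members, 47 in all (the pancreas acinar list had too few), were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry (limma 3.58.1). The rule named, per direction, genes that passed, or else the 5 with the smallest p as values only (fewer for resveratrol against control), with a mean of at least 1 CPM and a symbol that is no predicted gene, clone or antigen receptor segment. It added up to 4 members with the smallest p from each list that passed, of which a selection is given, and the fixed genes Lep, Adipoq, Sirt1, Ccl2, Adgre1 and Ucp1. Percentages of the obesity mean are medians over list members that averaged 1 CPM or more in obesity. Marker genes given outside it were chosen after their values were seen. The overlap of the diet and resveratrol differences was set beside 20 simulations of unchanged groups that share the obesity libraries.

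The fits were tested on simulated data with 100 genes changed by each fold. With the spread of all 5 libraries, 16-fold changes were recovered for 26% of genes in obesity against control (22861 genes run), 63% in resveratrol against obesity (22968) and 44% in resveratrol against control (22896). For 4-fold changes these shares were 1%, 6% and 3%. Alternatives were median-ratio size factors, no filter and a stricter filter on low counts, DESeq2 1.42.0, limma-voom, a fit that is not robust, only the groups compared, a replicate block, a further log2 threshold of 1, and leaving out libraries. Leaving out the control and resveratrol 1 libraries together was added after seeing the data. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.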

Results

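Messenger RNA of visceral adipose tissue was measured in 5 libraries from male C57BL/6 mice, an inbred laboratory strain. The control group had 1 library from a mouse on standard chow, given vehicle per its label. Per the labels, mice were 8 weeks old at the start of the diet and 16 weeks old at the start of treatment. The obesity group had 2 libraries from mice given a diet with 60% of its energy from fat for 8 weeks before vehicle. The resveratrol group had 2 libraries from mice on that diet which then received resveratrol, a plant polyphenol, at 2.25 mg/kg by gastric tube each day for 28 days. The deposited table gave whole-number counts for 78334 gene identifiers, and 24779 genes had enough counts to be tested. The total count was 27026597 in the control library. It was 19540961 and 21690850 in obesity libraries 1 and 2, and 21646089 and 26486024 in resveratrol libraries 1 and 2. Levels are TMM-scaled CPM, the count of a gene relative to its library's effective total, and ± is an SD over the 2 libraries of a group unless it is called a standard error (SE). The control group has no replicates. The labels do not state that the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries. Intervals and floors cover counting error alone.

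The 5 libraries did not hold the same tissue transcripts. In the control library the most abundant gene was Gpx5, a glutathione peroxidase secreted by the epididymis, the duct that stores sperm, at 28097 CPM (95% exact interval 28036 to 28157). Gpx5 stood at 10.96 CPM in obesity library 1, 0.182 CPM in resveratrol library 1, and at a count of 0 in obesity library 2 and resveratrol library 2, where 3 counts correspond to 0.143 and 0.117 CPM. The 12 genes of the epididymis list, fixed before the data were examined, summed to 40132 CPM in the control library and to 8.09 and 0.238 CPM in the obesity libraries. The 20 genes of the adipocyte identity list summed to 808 CPM in the control library, against 48628 and 58920 CPM in the obesity libraries. In resveratrol library 1 the epididymis list summed to 3409 CPM, of which Crisp1, a secretory protein gene of the male tract, made up 3397 CPM. Adipoq, the gene for the adipocyte hormone adiponectin, was at 14.2 CPM in the control library and at 1225 and 1587 CPM in the obesity libraries.

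Resveratrol library 1 also stood apart from its partner. Its most abundant gene was Myh11, the smooth muscle myosin heavy chain, at 19257 CPM (95% exact interval 19200 to 19315), against 34.8 CPM in resveratrol library 2 and 137 and 22.6 CPM in the obesity libraries. The smooth muscle and pericyte list summed to 44723 CPM there and to 735 CPM in resveratrol library 2. The median member of the adipocyte identity list stood at 17.9% of its obesity mean in resveratrol library 1 and at 112% in resveratrol library 2. For the pan-macrophage list these medians were 19.7% and 99.6%. Across genes, log2 CPM correlated at 0.964 between the obesity libraries, 0.977 between obesity library 2 and resveratrol library 2, and 0.868 between the resveratrol libraries. The control library correlated with the others at 0.698 to 0.788. These correlations are across genes, which are not independent replicates. Gpx5 and Myh11 were chosen after their values were seen.

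**Figure D1:**
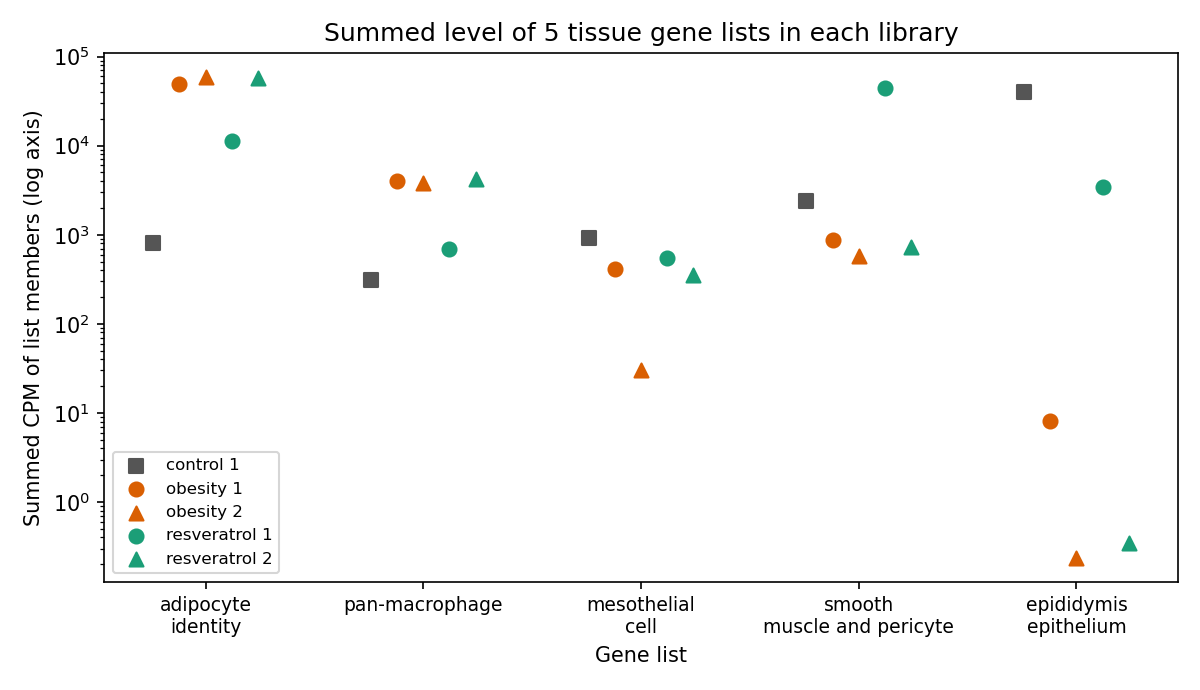
Summed CPM of the members of 5 gene lists (horizontal axis) in each of the 5 libraries (vertical axis, log scale); each point is 1 library, coloured by group. Adipocyte identity genes sum to 808 CPM in the control library and 48628 CPM in obesity library 1, epididymis genes to 40132 and 8.09 CPM, and smooth muscle genes to 44723 CPM in resveratrol library 1.

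The first comparison asked how visceral fat of mice on the high-fat diet differed from that of the lean control. Most adipocyte, lipolysis, triglyceride synthesis, matrix and macrophage genes stood far higher in both obesity libraries than in the control library, and epididymal genes far lower. Lep, the gene for the appetite hormone leptin, was at 2952 ± 168 CPM (SD, n = 2) in obesity and 9.69 CPM in control, a log2 difference of 8.25 with an SE of 2.16. No single gene passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, and the smallest adjusted p was 0.0999. In that test 6018 of 24779 genes had an unadjusted p under 0.05. By the same threshold DESeq2 called 4288 genes and limma-voom 0. Every gene value below is therefore a level and a difference, not a call.

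The 5 higher genes with the smallest p were Bmp3, Kcnk3, Adap1, Adra1d and Itgad. Bmp3 (ENSMUSG00000029335), a bone morphogenetic protein gene, had a count of 0 in the control library and 60.9 ± 1.33 CPM in obesity, at least 582-fold higher against a floor of 3 counts. Kcnk3 (ENSMUSG00000049265), which encodes a potassium leak channel, was likewise at 0 counts in control and at 142 ± 24.7 CPM in obesity, at least 1361-fold higher. Itgad, an integrin subunit gene of leukocytes, was at 0 counts in control and 251 and 157 CPM in the obesity libraries. Adap1 differed by 7.44 on the log2 scale (SE 0.458) and Adra1d, an alpha-1 adrenergic receptor gene, by 6.85 (SE 0.514). The 5 lower genes were Slc17a9, Gstm7, Arnt2, Tecta and Sytl4. Slc17a9 (ENSMUSG00000023393), the vesicular nucleotide transporter gene, was at 259 CPM in control and at 5.58 and 5.28 CPM in the obesity libraries. Gstm7, a glutathione S-transferase gene, was at 877 CPM in control and at 3.70 and 3.86 CPM in obesity.

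Of 47 gene lists tested with camera on the edgeR fit, 26 passed an adjusted p of 0.05, 23 of them upward and 3 downward. None of the 26 held with an estimated correlation, where the smallest adjusted p was 0.731 with an estimated correlation. Fry called 0 lists, with a smallest adjusted p of 0.325. The adipocyte identity list rose, with all 20 members higher in obesity and a median difference of 85.2-fold (camera adjusted p = 2.96e-08, and adjusted p = 0.731 with an estimated correlation). Adjusted over the list alone, 20 of its members passed, and 0 adjusted over all genes. Retn, the gene for the adipokine resistin, was at 960 ± 18.1 CPM in obesity and 25.1 CPM in control, and the insulin-responsive glucose transporter gene Slc2a4 was at 148 ± 41.6 and 14.6 CPM. Lipolysis genes rose, with all 15 higher and 12 passing when adjusted over the list alone. Among them Cav1, a coat protein gene of caveolae, was at 2225 ± 146 CPM in obesity and 58.0 CPM in control. Fatty acid oxidation genes rose with a smaller median difference of 3.82-fold, all 20 members being higher. Acadvl, the very long chain acyl-CoA dehydrogenase gene of that pathway, was at 91.8 ± 5.23 and 12.7 CPM.

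Triglyceride synthesis rose as a list, with 15 of 16 members higher and a median difference of 17.9-fold. Camera gave the list adjusted p = 6.38e-05, and adjusted p = 0.731 with an estimated correlation, and 0 members passed when adjusted over the list alone. Its member Gpat3, which encodes an enzyme of the first acylation step, was at 92.2 ± 0.0898 CPM in obesity and 1.43 CPM in control. In the adipokine list 17 of 19 members were higher and 11 passed when adjusted over the list alone. Its member Sfrp1, a secreted Wnt inhibitor gene, went the other way, at 3.44 ± 0.0111 CPM in obesity and 25.6 CPM in control. Nuclear-encoded oxidative phosphorylation rose with a median difference of 1.70-fold, 27 of 33 members being higher. Insulin signalling rose, with 15 of 16 members higher. The remaining member, Enpp1, an ectonucleotide pyrophosphatase gene, was at 8.45 ± 1.78 CPM in obesity and 417 CPM in control. In the thermogenic list 12 of 16 members were higher. Ucp1, the uncoupling protein gene of brown fat, was at 88.6 CPM in obesity library 1 and 0.381 CPM in obesity library 2.

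Macrophage and other immune lists rose as well. The adipocyte identity list itself differed by 85.2-fold from this control library. The immune differences, and those of the matrix and cell cycle lists below, therefore cannot be parted from its low level of fat tissue genes. The same holds for the lipolysis, fatty acid oxidation, triglyceride synthesis, adipokine, oxidative phosphorylation, insulin signalling and thermogenic lists above. It also holds for the endothelial, p53, autophagy and liver lists below. The pan-macrophage list had 15 of 16 members higher and a median difference of 11.4-fold (camera adjusted p = 0.000172, and adjusted p = 0.731 with an estimated correlation). Its fixed member Adgre1, which encodes the macrophage marker F4/80, was at 249 ± 14.3 CPM in obesity and 6.63 CPM in control. Lipid-associated macrophage genes had a median difference of 24.0-fold. Spp1, the osteopontin gene, was at 38.1 ± 2.79 CPM in obesity and 0.976 CPM in control, and the lipid droplet gene Plin2 was at 1628 ± 144 and 10.6 CPM. Among alternatively activated macrophage genes the lectin gene Clec10a was at 232 ± 30.5 and 1.60 CPM. The inflammatory cytokine list had 16 of 21 members higher. Ccl2, a monocyte-attracting chemokine gene, was at 28.2 ± 3.53 CPM in obesity and 0.314 CPM in control, a log2 difference of 6.46 (SE 1.53). Against the direction of that list, the lipocalin gene Lcn2 was at 4613 CPM in control and 3.59 ± 1.57 CPM in obesity. Lcn2 made up most of the 4630 CPM of that list in control. Whether it came from other tissue in that library was not tested. Mast cell, B cell, dendritic cell, MHC class II and interferon response lists also passed upward, with camera adjusted p from 0.0152 to 0.0464 and adjusted p of 0.731 to 0.734 with an estimated correlation.

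The extracellular matrix list rose, with all 23 members higher and a median difference of 19.4-fold (camera adjusted p = 5.11e-08, and adjusted p = 0.731 with an estimated correlation). Col6a3, a collagen VI chain gene, was at 647 ± 127 CPM in obesity and 20.7 CPM in control, and the matrix metalloproteinase gene Mmp2 was at 74.3 ± 9.07 and 3.21 CPM. All 18 cell cycle genes were higher, with a median difference of 4.78-fold, and 0 of them passed when adjusted over the list alone. The endothelial list had 12 of 12 members higher, the p53 and senescence list 11 of 13, the autophagy and lysosome list 14 of 16, and the liver list 10 of 11. Of the liver genes Cyp2e1, a cytochrome P450 gene, was at 308 ± 185 CPM in obesity and 20.2 CPM in control. The 3 lists that fell were epididymis epithelium, testis germ cell and cytosolic ribosomal protein. All 12 epididymis genes were lower in obesity, with a median difference of 11429-fold. Cst8, a cystatin gene of the male reproductive tract, was at 1559 CPM in control and 0.126 ± 0.0433 CPM in obesity. Among germ cell genes Smcp, a sperm mitochondrial protein gene, was at 54.5 CPM in control. Ribosomal protein genes had a median difference of 1.71-fold, 31 of 32 being lower. Ribosomal protein genes have many near-identical pseudogene copies that can take their reads, so their levels are uncertain.

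De novo lipogenesis did not pass (camera adjusted p = 0.262), with 12 of 18 members higher. Against that majority the citrate lyase gene Acly was at 651 CPM in control and 159 and 263 CPM in obesity, and Fads2 was at 386 CPM and 25.5 and 18.7 CPM. The control library held epididymal transcripts, so the high control levels of Acly, Fads2, Lcn2, Enpp1 and Sfrp1 need not be those of lean fat.

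The SIRT1 and AMPK list, which covers the targets most often linked to resveratrol, did not pass (camera adjusted p = 0.140). Sirt1 was at 20.5 ± 3.79 CPM in obesity and 19.8 CPM in control, a log2 difference of 0.05 (SE 0.359) that lay within the spread. The count of genes called in this comparison depended on the resveratrol libraries, which set part of the spread. It was 9227 without resveratrol library 1 and 9094 without resveratrol library 2. The control library, with its epididymal transcripts, was the sole lean library and could not be left out.

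The second comparison asked how resveratrol changed visceral fat on the high-fat diet. The genes with the smallest p lay on one side in both resveratrol libraries and on the other in both obesity libraries. Sfrp1 (ENSMUSG00000031548) was at 51.9 and 47.5 CPM in the resveratrol libraries and at 3.44 and 3.43 CPM in the obesity libraries, a log2 difference of 3.85 (SE 0.263). Hoxc10 (ENSMUSG00000022484), a posterior homeobox gene, was at 1.04 and 0.350 CPM with resveratrol and at 23.3 and 26.2 CPM without, a log2 difference of -5.15 (SE 0.712). No gene passed in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.899 and 581 of 24779 genes had an unadjusted p under 0.05. DESeq2 called 212 genes and limma-voom 0.

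The 5 higher genes with the smallest p were Sfrp1, Fmod, Aebp1, Ptgis and Tmem151a. Fmod, the gene for the collagen-binding proteoglycan fibromodulin, was at 72.8 ± 14.8 CPM with resveratrol and 4.92 ± 0.424 CPM in obesity. Aebp1, which encodes a matrix carboxypeptidase-like protein, was at 243 ± 8.46 and 47.7 ± 1.57 CPM. Ptgis, the prostacyclin synthase gene, was at 43.2 ± 8.19 and 5.56 ± 1.15 CPM. Tmem151a, which encodes a membrane protein, was at 18.6 ± 3.81 and 1.55 ± 0.171 CPM. The 5 lower genes were Itgad, Pla2g5, Gnal, Hoxc10 and Tbx15. Itgad (ENSMUSG00000070369) was at 2.91 ± 1.16 CPM with resveratrol and 204 ± 66.3 CPM in obesity, a log2 difference of -6.12 (SE 0.532). Pla2g5, a secreted phospholipase A2 gene, was at 1.11 ± 0.352 and 13.7 ± 2.96 CPM. Gnal, a G protein alpha subunit gene, was at 1.59 ± 0.767 and 31.8 ± 10.2 CPM. Tbx15, a T-box transcription factor gene, was at 0.415 ± 0.0731 and 5.97 ± 0.703 CPM. For Hoxc10, Tbx15 and the other genes named here, resveratrol treatment and a difference in the depot or tissue sampled cannot be told apart. In 34.0% of tested genes both resveratrol libraries lay on the same side of both obesity libraries, and chance gives 33.3%.

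**Figure D2:**
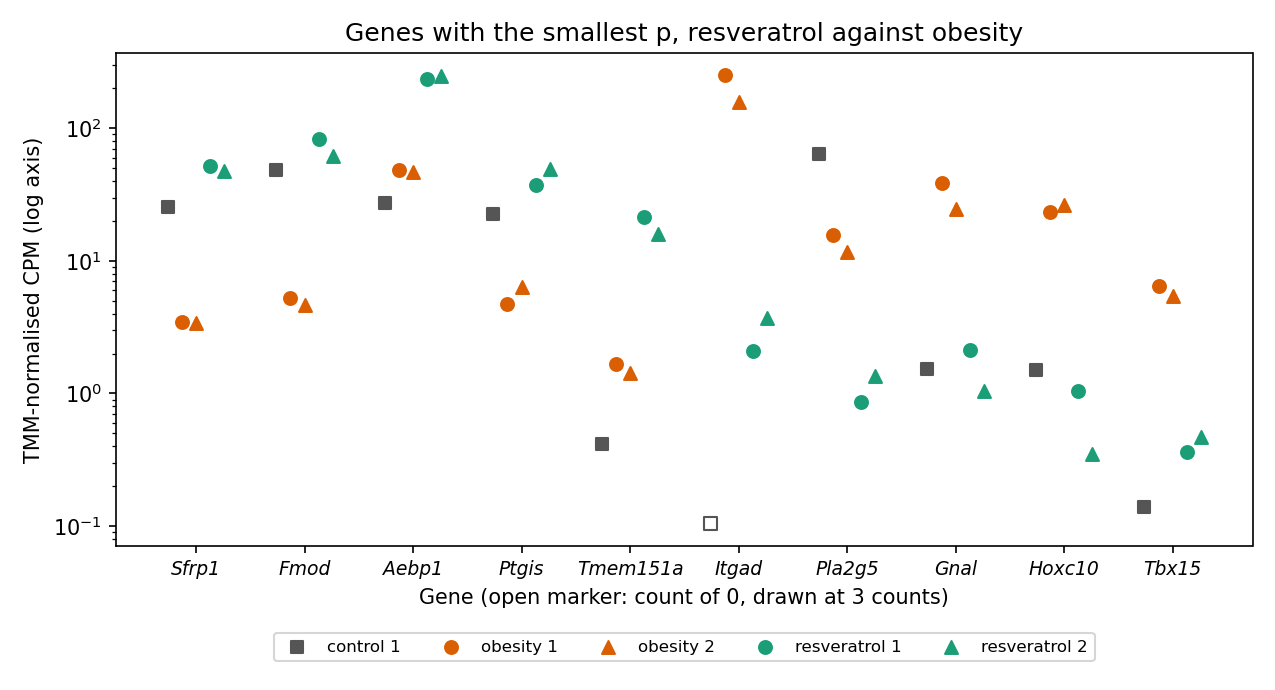
CPM (vertical axis, log scale) of the 10 genes with the smallest unadjusted p for resveratrol against obesity (horizontal axis); each point is 1 library, and an open marker is a count of 0 drawn at the level of 3 counts. Sfrp1 lies at 51.9 and 47.5 CPM with resveratrol against 3.44 and 3.43 CPM in obesity, and Hoxc10 at 1.04 and 0.350 against 23.3 and 26.2 CPM; none of the 10 passed the adjusted test.

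Of 47 lists, 21 passed with camera, 5 upward and 16 downward. None of them held with an estimated correlation, every one of the 21 having adjusted p = 0.867 with an estimated correlation, and fry called 0 (smallest adjusted p 0.774). Cell cycle genes fell, with all 18 members lower and a median difference of 2.08-fold (camera adjusted p = 5.25e-09, and adjusted p = 0.867 with an estimated correlation). Pcna, the DNA polymerase clamp gene, was at 16.9 and 24.8 CPM with resveratrol and 49.5 and 37.3 CPM in obesity, and the mitotic kinase gene Cdk1 was at 4.36 and 8.79 against 19.8 and 15.5 CPM. Lipid-associated macrophage genes fell, all 16 being lower, with Spp1 at 8.59 and 16.6 CPM with resveratrol and 40.1 and 36.2 CPM in obesity. The median member of this list stood at 13.7% of its obesity mean in resveratrol library 1 and 73.9% in resveratrol library 2, and that of the cell cycle list at 30.0% and 66.6%. Fatty acid oxidation genes fell, 19 of 20 being lower, with medians of 48.8% and 81.8% of the obesity mean in resveratrol libraries 1 and 2. The mitochondrial carnitine carrier gene Slc25a20 was at 43.5 and 65.4 CPM against 99.2 and 81.0 CPM. The NRF2 antioxidant list fell, 14 of 18 members being lower, with medians of 68.8% and 84.9%. In it Hmox1, the heme oxygenase 1 gene, was at 39.3 and 91.2 CPM against 165 and 155 CPM, and the cystine transporter gene Slc7a11 was at 1.04 and 1.24 against 2.40 and 1.90 CPM. The thermogenic list fell, with 13 of 16 lower, and its member Ucp1 was high in obesity library 1 alone.

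In several further lists that fell, as in some of those above, resveratrol library 1 lay far below resveratrol library 2. Adipocyte identity had 17 of 20 members lower (camera adjusted p = 0.00727, and adjusted p = 0.867 with an estimated correlation), yet its direction was upward without resveratrol library 1, with camera adjusted p = 0.435, and without obesity library 2 its camera adjusted p was 0.0972. Without resveratrol library 1, 20 lists passed, 13 of them among the 21 and 4 with the opposite direction. Adipoq was at 266 and 1699 CPM in resveratrol libraries 1 and 2, and Lep at 277 and 2473 CPM. The pan-macrophage list had 14 of 16 members lower, and Adgre1 was at 23.4 and 223 CPM; without resveratrol library 1 its camera adjusted p was 0.834. Triglyceride synthesis, lipolysis, extracellular matrix and de novo lipogenesis passed downward too. The median member of these lists stood at 20.0%, 25.9%, 30.2% and 29.8% of its obesity mean in resveratrol library 1, and at 94.8%, 106%, 105% and 103% in resveratrol library 2. Within the matrix list Fn1, the fibronectin gene, was higher, at 605 and 1593 CPM with resveratrol against 197 and 286 CPM in obesity. Within the lipogenesis list the desaturase gene Fads2 was at 1025 CPM in resveratrol library 1 and at 24.9 CPM in resveratrol library 2, against 25.5 and 18.7 CPM in obesity. Cholesterol synthesis, unfolded protein response, autophagy and lysosome, oxidative phosphorylation and ribosomal protein lists fell by small amounts, with median differences of 1.28, 1.19, 1.20, 1.11 and 1.14-fold. The last pair did not part in that way, with medians of 95.6% and 86.3% of the obesity mean in resveratrol libraries 1 and 2 for oxidative phosphorylation, and 97.6% and 84.9% for ribosomal protein. Herpud1 of the unfolded protein response list was higher in resveratrol library 1 at 215 CPM and at 61.8 CPM in resveratrol library 2, against 60.0 and 67.9 CPM in obesity.

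The 5 lists that rose were mast cell, lymph node, B cell and plasma cell, mesothelial cell, and adipose stem and progenitor cell. All 10 mast cell genes were higher, with a median difference of 3.58-fold (camera adjusted p = 9.39e-06, and adjusted p = 0.867 with an estimated correlation). Kit, the stem cell factor receptor gene, was at 29.4 and 18.2 CPM with resveratrol and 6.26 and 7.66 CPM in obesity, and the chymase gene Cma1 was at 21.9 and 10.3 against 4.43 and 3.05 CPM. The median mast cell gene stood at 432% and 250% of its obesity mean in resveratrol libraries 1 and 2. Mesothelial genes, of the cell layer that lines the abdominal organs, were higher in 12 of 13 cases, with medians of 172% and 730%. Gpm6a, a membrane glycoprotein gene, was at 27.9 and 31.5 CPM with resveratrol and 0.522 and 1.43 CPM in obesity. Of the 13 members 9 were highest in resveratrol library 2. Upk3b was at 2.50 CPM in resveratrol library 1 and 108 CPM in resveratrol library 2, against 23.6 and 6.00 CPM in obesity. Of the progenitor list 11 of 16 members were higher and 5 passed when adjusted over the list alone. Its median member stood at 105% of its obesity mean in resveratrol library 1 and 164% in resveratrol library 2. Among the higher members Pi16 was at 28.1 and 45.4 CPM with resveratrol against 8.87 and 8.28 CPM, and Dpp4, both known markers of early adipose progenitors, was at 29.7 and 32.8 against 7.04 and 10.7 CPM. All 6 tested lymph node genes were higher, among them the chemokine gene Ccl21a at 40.02 and 10.7 CPM against 1.83 and 3.24 CPM. Ccl21a made up most of the 44.3 CPM of that list in resveratrol library 1, and 1 member averaged 1 CPM or more in obesity. Cxcl13 was at 0.136 CPM in resveratrol library 1 and 8.29 CPM in resveratrol library 2, against 1.04 and 0.809 CPM in obesity. Of the B cell list 11 of 13 were higher, yet it summed to 107 and 970 CPM in resveratrol libraries 1 and 2, against 612 and 649 CPM in obesity. Its median member stood at 43.6% and 171% of its obesity mean in those resveratrol libraries, among members at 1 CPM or more in obesity. For these 5 lists, too, resveratrol treatment and a difference in the depot or tissue sampled cannot be told apart.

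**Figure D3:**
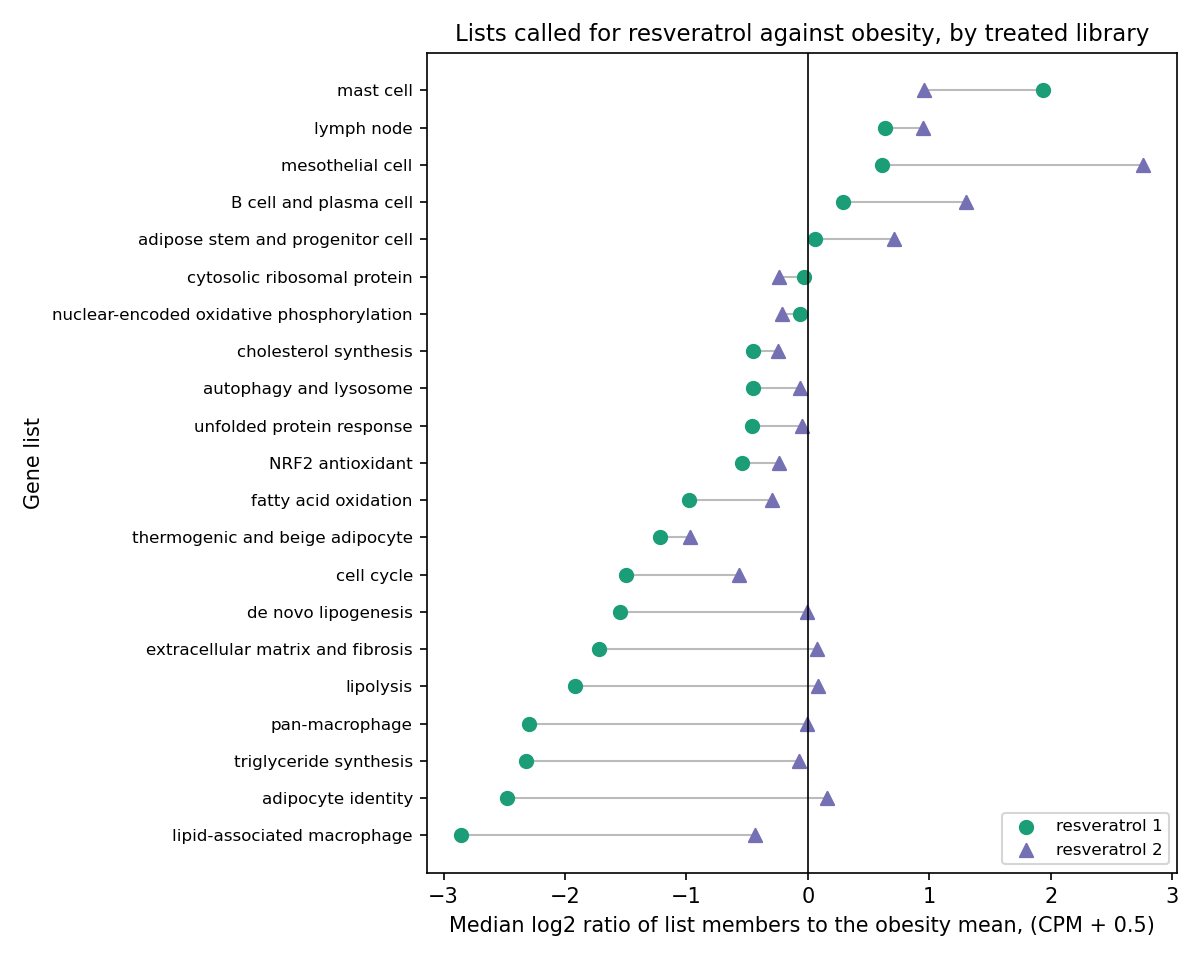
Median log2 ratio of the members of each list to their obesity mean, computed on CPM + 0.5 (horizontal axis), for the 21 lists that camera called for resveratrol against obesity (vertical axis); circles are resveratrol library 1 and triangles resveratrol library 2. The adipocyte identity median stands at -2.48 in resveratrol library 1 and 0.16 in resveratrol library 2, and the mesothelial median at 0.61 and 2.76.

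The SIRT1 and AMPK list did not pass (camera adjusted p = 0.639), with 13 of 21 members higher. Sirt1 was at 17.2 ± 1.53 CPM with resveratrol and 20.5 ± 3.79 CPM in obesity, a log2 difference of -0.25 (SE 0.293), and Ccl2 was at 5.54 and 30.96 CPM against 25.7 and 30.7 CPM. Neither difference exceeded the spread between libraries. The inflammatory cytokine list did not pass either (camera adjusted p = 0.992), and its median was negative while its mean was positive. Test, median and mean also differed in sign for other lists that did not pass, among them adipokines and endothelial cell here and smooth muscle in the first comparison. The count of called genes was 33 without resveratrol library 1, 4758 without resveratrol library 2, and 25 with no filter on low counts. Chosen after seeing the data, a fit of both obesity libraries against resveratrol library 2, without the control and resveratrol 1 libraries, called 66 genes, 55 higher and 11 lower. Its call with the smallest p was not shared by resveratrol library 1. Slpi, a secreted protease inhibitor gene, was at 211 CPM in resveratrol library 2 and 1.36 CPM in resveratrol library 1, against 4.59 and 3.76 CPM in obesity. Of the 66 calls 38 lay on the same side of obesity in resveratrol library 1, a count for which no value for unchanged groups was computed. In that fit the log2 difference was 3.80 for Sfrp1, -6.11 for Hoxc10 and -5.76 for Itgad. Tbx15 was at 0.467 CPM in resveratrol library 2 against 6.47 and 5.47 CPM in obesity. These genes were named for a small p over all 5 libraries, which include those of that fit, so their values here are no separate support. The fit chosen after seeing the data has 1 residual degree of freedom and takes its spread from the obesity pair.

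The third comparison asked how far the treated tissue lay from the lean control. As in the first comparison, most adipocyte and matrix genes were far higher than in the control library and epididymal genes far lower. Bmp3 was at 89.4 ± 6.77 CPM with resveratrol and at a count of 0 in control, at least 854-fold higher, and Kcnk3 was at least 1164-fold higher. Adap1 and Adra1d followed, with log2 differences of 7.26 (SE 0.455) and 7.46 (SE 0.528). Slc17a9, Lipg, Gstm7 and Tecta were the lower genes with the smallest p. Lipg, the endothelial lipase gene, was at 147 CPM in control and at 0.909 and 0.817 CPM with resveratrol. Tecta, the gene for a matrix protein of the inner ear, was at 71.1 CPM in control and at 0.136 and 0.117 CPM with resveratrol. No gene passed in edgeR's quasi-likelihood test (smallest adjusted p 0.134), where 4596 of 24779 genes had an unadjusted p under 0.05. DESeq2 called 2970 genes and limma-voom 80, all lower with resveratrol.

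Of 47 lists, 25 passed with camera, 21 upward and 4 downward, none of them with an estimated correlation (smallest adjusted p = 0.635 with an estimated correlation) and 0 with fry. Adipocyte identity rose, all 20 members being higher with a median difference of 52.6-fold and 18 passing when adjusted over the list alone. Adipoq was at 983 ± 1014 CPM with resveratrol and 14.2 CPM in control. Matrix genes rose, 22 of 23 being higher, with Col6a3 at 334 ± 87.7 and 20.7 CPM. Mast cell genes rose, all 10 being higher and 7 passing when adjusted over the list alone, with Cma1 at 16.1 ± 8.19 and 0.0697 CPM. De novo lipogenesis (11 of 18 higher) and cholesterol synthesis (12 of 18 lower) did not pass, with camera adjusted p of 0.565 and 0.154. The circadian clock list passed here and not in the other comparisons, a difference that was not itself tested. Its member Nr1d1, which encodes the nuclear receptor REV-ERB alpha, was at 207 ± 31.5 CPM with resveratrol and 17.4 CPM in control. T cell and lymph node lists also passed upward (camera adjusted p = 0.0435 and 0.0210). The lists that fell were epididymis epithelium, testis germ cell, ribosomal protein and unfolded protein response. In the last of these 10 of 14 members were lower, and Creld2, a gene of endoplasmic reticulum stress, was at 27.5 ± 1.65 CPM with resveratrol and 141 CPM in control. The count of called genes was 7469 without resveratrol library 1 and 4199 without resveratrol library 2. The control library, with its epididymal transcripts, could not be left out. These differences, too, cannot be parted from its low level of fat tissue genes.

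The last comparison asked whether genes that differed with the diet moved back with resveratrol. Sfrp1 did so in level, at 25.6 CPM in control, 3.44 ± 0.0111 CPM in obesity and 49.7 ± 3.10 CPM with resveratrol. Itgad and Hoxc10 went from a count of 0 and 1.4995 CPM in control to 204 ± 66.3 and 24.8 ± 2.02 CPM in obesity, and to 2.91 ± 1.16 and 0.697 ± 0.491 CPM with resveratrol. The control library held epididymal transcripts and little adipocyte RNA, so its levels need not be those of lean fat. Sfrp1, Itgad and Hoxc10 were named for a small p in resveratrol against obesity, so they are no test of a return. No gene was called in both comparisons by edgeR's quasi-likelihood test, since neither called any gene. With DESeq2, 106 genes were called in opposite directions, against 19.8 for independent lists, and 3 in the same direction. Across all 24779 genes the covariance of the diet difference and the resveratrol difference in log2 CPM was -1.28. Both differences use the same obesity libraries, which alone gave a simulated covariance of -0.443 for unchanged groups with the spread of all 5 libraries, a difference of -0.841. With the spread of the obesity pair the simulated covariance was -0.135, and the spread of that pair itself gives -0.228. With resveratrol library 1 alone the covariance was -2.45, and with resveratrol library 2 alone it was -0.113. With 1 obesity library in each difference it was -1.20 or -0.910, and with resveratrol library 2 alone in that split it was -0.152 or 0.381. Without resveratrol library 1, edgeR called 17 genes in opposite directions, against 6.02 for independent lists, and 11 in the same direction. Without resveratrol library 2 it called 3426, against 887. Part of any excess may come from the shared obesity libraries. The control library and resveratrol library 1 were also both low in fat genes. The median adipocyte identity gene stood at 1.17% and 17.9% of its obesity mean in them, and at 112% in resveratrol library 2. For the pan-macrophage list these medians were 8.74%, 19.7% and 99.6%. Opposite directions with resveratrol library 1 need therefore not be a return toward lean fat.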

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

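Leaving out the control and resveratrol 1 libraries together was chosen after seeing the data; the other alternatives were planned. For obesity against control, 0 genes were called (edgeR; 6018 at an unadjusted p under 0.05), also with median-ratio size factors, a stricter filter, limma-voom, a fit that is not robust and a further log2 threshold. The count was 2575 with no filter on low counts, 4288 with DESeq2 and 9269 with only the groups compared, and 0 to 9227 over the libraries left out. For resveratrol against obesity (581 unadjusted) it was 25, 212 and 0 in those settings, 66 with the control and resveratrol 1 libraries left out together, and 0 to 4758 with 1 left out. For resveratrol against control (4596 unadjusted) it was 1671, 2970 and 0, 80 with limma-voom, and 0 to 7469. The fits with only the obesity pair as replicates take their spread from it, 31.9% against 62.2% over all 5 libraries; why no filter and DESeq2 call more was not tested. Genes called in opposite directions numbered 15 with no filter, 106 with DESeq2 and 0 to 3426 with 1 library left out.

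With an estimated correlation 0 lists were called in each comparison, and with fry 0, against 26, 21 and 25. With 1 library left out these were 23 to 25, 15 to 25 and 22 to 29. In the fit chosen after seeing the data 24 lists passed for resveratrol against obesity, of which 0 held with an estimated correlation. Of those 24 lists 13 were among the 21, and 6 had the opposite direction. Without obesity library 2, 12 of the 15 lists were among the 21. With the replicate block 0 genes were called in each comparison, and 24, 27 and 26 lists. The same-numbered libraries' deviations correlated at 0.282 over 2 pairs, too few to decide whether the numbers pair the samples, and the labels give no shared animal or day.

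Of 160 values for named genes, 54 kept their side of the threshold with DESeq2 and 106 passed it, while 160 kept it in the fit that is not robust. On the log2 scale, the result for Sirt1, obesity against control, was -0.00332 with median-ratio size factors, -0.0865 with the stricter filter, and -0.13 to 0.23 with 1 library left out. The result for Adipoq, resveratrol against obesity, was 0.28 with the control and resveratrol 1 libraries left out together and -2.40 to 0.29 with 1 left out. That for Ccl2, resveratrol against obesity, was 0.15, and -2.34 to 0.15. That for Herpud1, resveratrol against obesity, was -0.0404, and -0.0392 to 1.75. Ucp1, resveratrol against control, was at 1.36 with the replicate block. The cause of these reversals was not tested beyond the libraries named. Depth limits genes under about 0.157 CPM.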

Other observations

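All tests in this part, and its genes outside the lists fixed beforehand, were chosen after the values were seen. Several genes stood above both obesity libraries in resveratrol library 2. The median gene of the immediate-early and dissociation stress list stood at 238% of its obesity mean there, and at 83.6% in resveratrol library 1. For the endothelial list these medians were 174% and 34.6%. Of the 13 mesothelial genes 9 were highest in resveratrol library 2, though the list summed to 351 CPM there. It summed to 915 CPM in control, 548 CPM in resveratrol library 1 and 408 CPM in obesity library 1. Slpi, a secreted protease inhibitor gene, was at 211 CPM against 4.59 and 3.76 CPM in obesity, and Prg4, the lubricin gene, was at 181 CPM against 8.61 and 12.2 CPM. In resveratrol library 1 they were at 1.36 CPM each. The mesothelial genes Msln and Upk3b were at 65.4 and 108 CPM in resveratrol library 2, and at 1.82 and 2.50 CPM in resveratrol library 1. Alox15, a lipoxygenase gene, was at 148 CPM and under 0.9 CPM in each other library, and Timd4, a receptor gene of resident macrophages, was at 8.87 CPM against 0.209 and 0.571 CPM in obesity. Cd79a, a B cell receptor signalling gene, was at 7.35 CPM against 0.678 and 0.666 CPM. Eln, the elastin gene, was at 293 CPM against 102 and 74.2 CPM. In obesity library 1, 6 urothelial genes summed to 409 CPM, against 0.238 CPM in obesity library 2. They summed to 93.6 CPM in control, 57.1 CPM in resveratrol library 1 and 0.856 CPM in resveratrol library 2. Ucp1 was at 88.6 CPM in obesity library 1 (95% exact interval 84.5 to 93.0). Genes of the seminal vesicle and prostate summed to at most 1.27 CPM in every library.

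Adipocyte genes were low in the control library. Lower sequencing depth would need a smaller library, but its total count was 121% of the mean of the others. A lean diet with no other tissue would leave epididymis genes low, and 12 of the 12 were above 100 CPM. Tissue of the epididymis in the control library is a candidate explanation, as 10 of the 12 genes stood at least 100 times above every other library, and 1 of them averaged 1 CPM or more in obesity. How much of each difference from control belongs to the diet stays open.

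Adipocyte genes were also low in resveratrol library 1. An effect of resveratrol shared by both treated libraries is argued against by resveratrol library 2, where the median adipocyte gene was at 112% of its obesity mean. Muscle-walled tissue in resveratrol library 1 may explain the pattern, since 6 of 10 smooth muscle genes stood at least 10 times above every other library, but Rgs5, Notch3, Cspg4 and the smooth muscle gene Actg2 did not, all 10 averaged 1 CPM or more in obesity, and the test does not decide. Tissue of the vas deferens in resveratrol library 1 could be its source, with Akr1b7 at 15288 CPM and 6 of 6 genes at least 10 times above every other library, though these genes were picked for that. An effect of treatment in this mouse alone was not tested.

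Hoxc10, Tbx15 and En1 were lower in resveratrol library 2 than in both obesity libraries. Fewer adipocytes are argued against by the median adipocyte gene at 112% of its obesity mean. Different fat depots in resveratrol library 2 and the obesity libraries stay open: 8 of 10 depot genes lay on the predicted side. But Tbx15 and En1 among them are the pattern itself, and Shox2 and Sfrp2 lay elsewhere. The depot genes were also listed after the data were seen. The subcutaneous depot genes Tbx15, En1 and Hoxc9 were higher in both obesity libraries than in resveratrol library 2. By these genes the obesity libraries would be the ones nearer to subcutaneous fat. Sfrp2 of the same list went the other way, at 64.6 CPM in resveratrol library 2 against 12.1 and 8.43 CPM in obesity. Which libraries would hold the other depot was not tested. All 5 libraries are labelled visceral. For resveratrol treatment, 3 of 3 genes lay below both obesity libraries in both treated libraries, which is no evidence, since the genes were picked for being low. Depot and resveratrol treatment cannot be told apart here, since no treated and untreated samples of a known common depot exist.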
